A study of Escherichia coli with 4 samples.

How the data were processed

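RNA abundance was measured in Escherichia coli K-12 MG1655 grown anaerobically in a chemostat (37 °C, 30 mM glucose, dilution rate 0.2 per h, pH 7.2, 95% nitrogen and 5% carbon dioxide, per the labels' protocols) and switched to air. Cells exposed to air for 5, 10, 15 or 60 min were compared with the anaerobic steady state, the control of every time. Labelled material from different groups was hybridised in pairs, as Cy3 and Cy5, to two-colour spotted arrays of 4608 spots, of which 298 were controls.

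The deposited scanner files hold the signal intensity and the local background intensity of 1 channel of 1 slide, quantified with ImaGene 5.1 and not background subtracted, per the file headers. Of the 32 scanner files, 20 were distinct, because the same 4 control files were deposited with every sample. They came from 10 slides and gave 2 Cy3 and 2 Cy5 files for each of the 5 groups. The deposited table holds, per the submitters' design text, log2 ratios that the authors made from the mean of each channel by LOWESS normalisation in GeneSight 4, with all replicates combined into 1 value per probe and time. That text gives 2 cultures per group, each with a dye swap. The headers do not tell which files came from the same culture, so each channel file entered singly with the dye as a covariate. Files of the same culture are technical repeats, which makes the p-values too small. The pairing of channels on a slide was also left out. Modelling it, with the slide as a random block, gave more calls against the control. The description of the 10 min sample gives 5 min as its time, whereas its title and source give 10 min, and it was used as 10 min.

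From the intensities, background was corrected with normexp (offset 50), values were taken as log2, and the 20 files were quantile normalised, with R 4.3.3, limma 3.58.1 and statmod 1.5.0. Spots that the scanner software marked as poor (mark 3) or negative (mark 4) were set to missing, and probes of the same gene were averaged. Names came from the platform table and, by gene identifier, from the RefSeq annotation ASM584v2. It named 4086 probes, a further 128 were named through the scanner file's own name, and 95 kept that name. Genes with at least 2 unmarked values in every group were tested, 3072 of 4211. The other 1139 were left out. The number of arrays limits the precision: the median standard error of a change against the control was 0.451 to 0.454 on the log2 scale.

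Each time was compared with the control, and 10 with 5, 15 with 10, 60 with 15 and 60 with 5 min, in 1 limma fit of all groups (two-sided moderated test, Benjamini-Hochberg adjustment over genes, adjusted p under 0.05). Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, adjusted over lists and times together, and again with an estimated correlation. Of 49 lists, 48 had at least 3 tested genes. Genes were named by a rule written before the data were examined: at each time the 10 largest rises and 10 largest falls among genes past the threshold, well above background in at least 1 group and with every exposed file beyond every control file, together with 40 preset genes (30 of them tested) and up to 4 members of each list, and between times the 5 largest rises and falls. A spot counted as well above background when its signal exceeded the local background mean by 2 background standard deviations. For naming, a group counted as such when at least 1 of its files did. The alternative below with only genes well above background instead required every measured file of at least 1 group. Where an entire group lay at background, the fold is given as a lower bound, with lower values raised to the lowest value well above background in their file, and no size is given where none was raised.

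The fit was repeated with the slide as a random block (consensus correlation of the channels of a slide 0.634) and with loess-normalised ratios within slides (2761 genes). Overlaps between times were set beside 50 simulations of unchanged groups against the same control files and beside the product expected of independent calls. The 4 control files stem from 2 cultures, so that the control could not be split into parts of at least 2 cultures. Other alternatives were no background correction, an offset of 10, cyclic loess, median centring, only genes well above background, only the groups compared, a minimum log2 change of 1, and each channel file left out in turn. Alternatives added after seeing the data were all spots whatever their mark, spots marked empty left out too, ratios within slides, leaving out slides 96 and 98, averaging dye-swap files under each of the 32 possible assignments to cultures, and 2 fits that follow chains of slides.

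The fit was tested on simulated data with 100 changed genes of each size among 3072. At a log2 change of 2 it recovered 71% of them at 5 min, 59% at 10 min, 66% at 15 min and 51% at 60 min. At a log2 change of 1 it recovered 7%, 12%, 9% and 5%. The false share of calls was 0%, 4.05%, 1.32% and 0%. A shifted list was called at every time, with no other of the 48 lists called. The simulated files were given no shared cultures and no chains of slides. These shares therefore do not measure the error in the real files.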

Results

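Transcript abundance was compared between an anaerobic steady state of E. coli MG1655 and 5, 10, 15 and 60 min of air, with 4 channel files in each of 5 groups. The median signal of a file ranged from 455 to 1417 intensity units and its median background from 119 to 421. Between 56.5% and 92.6% of the spots of a file lay well above background, and 24.2% to 30.7% were marked poor or negative. Each value below rests on 2 to 4 unmarked channel files per group, with errors given as the standard error of the fit.

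At 5 min of air, the question was which transcripts respond first. All 4 tested genes of cytochrome bo oxidase, the terminal oxidase used at high oxygen, had risen: cyoD by 12.4-fold (log2 3.64 ± 0.36, adjusted p = 2.25e-05), cyoC by 11.5-fold, cyoB by 10.8-fold and cyoA by 8.05-fold. The largest rises were those of trxC, encoding a thioredoxin of the OxyR regulon, by 16.5-fold (log2 4.04 ± 0.71, adjusted p = 0.00503), and sdhC, a subunit of succinate dehydrogenase, by 14.5-fold (log2 3.86 ± 0.59, adjusted p = 0.00166). The gene of the superoxide response regulator soxS rose by 8.81-fold (log2 3.14 ± 0.49). The largest falls included ydjX (at least 8.21-fold), the nitrite reductase gene nrfA (9.08-fold, log2 -3.18 ± 0.58) and the galactitol genes gatZ (6.83-fold, log2 -2.77 ± 0.38) and gatY (6.39-fold). In each of these genes every file at 5 min lay beyond every control file after correction for the dye. The rule for naming the largest rises and falls required this, so it is no separate support. The plot of values per file shows cyoB, soxS and gatZ among 6 genes.

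Among the lists at 5 min, counted over their tested members, 7 of 14 citric acid cycle genes rose and none fell (9 rose when adjusted over the list alone, camera adjusted p = 3.53e-15), among them icd (4.70-fold) and gltA (4.67-fold). Of the 8 Isc genes for iron-sulfur cluster assembly, 5 rose, with iscR by 7.12-fold and iscS by 5.73-fold (camera adjusted p = 4.33e-12). Pyruvate dehydrogenase had 3 of 4 genes higher, with aceE by 6.60-fold (adjusted p = 8.23e-08), and the OxyR regulon 5 of 11, with grxA by 7.28-fold and ahpC by 5.36-fold (adjusted p = 1.22e-09). The methionine biosynthesis list was higher (adjusted p = 1.22e-06; median log2 0.90), with 1 of its 12 genes past the gene test and 4 when adjusted over the list alone. Lower lists were glucose phosphotransferase uptake (1 of 6 genes, ptsH by 3.01-fold, adjusted p = 0.000126), nitrate and nitrite respiration (4 of 15, among them nirD by 6.23-fold and narG by 4.09-fold, adjusted p = 0.000303) and hydrogenases and formate hydrogenlyase (3 of 17, with hypB by 5.75-fold, adjusted p = 0.00195). The hydrogenase list had an adjusted p of 0.0537 when slides 96 and 98 were left out. Of their 4 files, 3 had the largest residual standard deviations of all.

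In all, 61 of 3072 genes passed at 5 min, 33 higher and 28 lower. The fit with the slide as a random block called 130 (66 higher, 64 lower) and ratios within slides called 61 of 2761 (38 higher, 23 lower). These are not the same 61 genes. Among the 58 called genes with a ratio within slides, 45 were called there and all 58 kept the sign. Without slides 96 and 98 the count was 38, and with dye-swap files averaged under the 32 possible assignments to cultures it was 12 to 55, with 10 of the 61 genes called in every assignment.

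**Figure D1:**
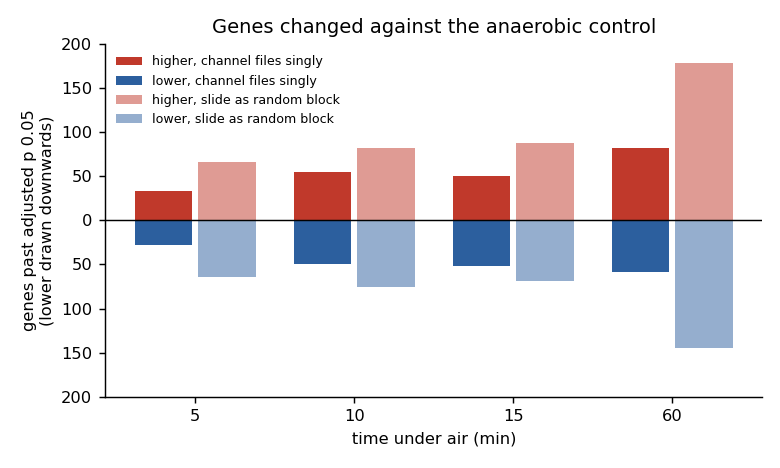
Number of genes past an adjusted p of 0.05 against the anaerobic control at each time under air, with higher genes drawn upwards and lower genes downwards, for channel files entered singly (dark) and with the slide as a random block (light). The single-file counts are 61, 104, 102 and 141 of 3072 genes.

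At 10 min, the fall of the galactitol transport and breakdown genes was the largest change: gatZ was 21.3-fold lower (log2 -4.41 ± 0.38, adjusted p = 4.98e-06), gatC 13.6-fold (log2 -3.77 ± 0.38) and gatB 7.23-fold, and gatY was lower too (log2 -3.58 ± 0.40). Also lower were nmpC (9.93-fold), ompW, an outer membrane protein (9.57-fold), nirD (9.70-fold) and yjjI (at least 5.39-fold). For nrfA, called lower, no size is given, since no file at 10 min lay well above background. Large rises were those of trxC (12.4-fold, log2 3.64 ± 0.67), cyoD (11.5-fold, log2 3.52 ± 0.33, adjusted p = 9.94e-06), soxS (10.6-fold) and iscR (10.4-fold). The sulfate binding protein gene sbp was 11.1-fold higher (adjusted p = 0.0121), with an adjusted p of 0.131 without the Cy3 file of slide 57 at 10 min.

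Citric acid cycle genes were higher at 10 min for 11 of 14 members (camera adjusted p = 1.89e-18), with icd by 5.60-fold, and so were 4 of 4 cyo genes (adjusted p = 5.14e-13), 6 of 8 Isc genes (adjusted p = 1.51e-12), 3 of 4 pyruvate dehydrogenase genes with aceE by 8.08-fold (adjusted p = 6.40e-07) and 5 of 11 OxyR genes with ahpC by 4.95-fold (adjusted p = 2.60e-06). The methionine list was higher with 4 of 12 genes past the gene test (adjusted p = 8.94e-06; median log2 1.02). Lower lists were glucose phosphotransferase uptake (3 of 6, adjusted p = 1.81e-05), hydrogenases (4 of 17, with hyaA by 4.47-fold, adjusted p = 9.97e-05) and nitrate and nitrite respiration (5 of 15, with narG by 6.37-fold, adjusted p = 0.000923). In all 104 genes passed, 55 higher and 49 lower. The slide block called 158 (82 higher, 76 lower), ratios within slides 52 (34 higher, 18 lower), and the assignments to cultures 17 to 120. Ratios within slides called 41 of the 93 called genes that had one, and all 93 kept the sign. Of the 104 genes, 16 were called in every assignment. No slide paired 10 min with the control.

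At 15 min, gatC was 21.6-fold lower (log2 -4.43 ± 0.39, adjusted p = 4.72e-06), gatZ 21.1-fold and gatY 14.4-fold, and hyaA, a hydrogenase subunit, was 7.22-fold lower (log2 -2.85 ± 0.38). The largest rises were those of soxS (14.6-fold, log2 3.86 ± 0.49, adjusted p = 0.000122), puuD, an enzyme of putrescine breakdown (14.1-fold, log2 3.82 ± 0.66), sbp (11.7-fold), cyoD (11.4-fold) and iscR (10.8-fold). The methionine synthase gene metE was 5.07-fold higher (log2 2.34 ± 0.44, adjusted p = 0.00433). Among the lists, the citric acid cycle (9 of 14 higher, adjusted p = 4.29e-18), Isc (6 of 8, adjusted p = 2.03e-15), cyo (4 of 4, adjusted p = 5.85e-14), pyruvate dehydrogenase (3 of 4, adjusted p = 4.28e-08), methionine (1 of 12, or 6 over the list alone, adjusted p = 7.99e-06) and OxyR (3 of 11, adjusted p = 0.00151) lists were higher.

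Lists lower at 15 min were hydrogenases (4 of 17, adjusted p = 6.40e-07), glucose phosphotransferase uptake (4 of 6, adjusted p = 1.39e-05), nitrate and nitrite respiration (4 of 15, adjusted p = 0.000207) and fumarate, DMSO and TMAO respiration (2 of 11, with frdB, a fumarate reductase subunit, 5.73-fold lower, adjusted p = 0.000415). In all 102 genes passed, 50 higher and 52 lower. The slide block called 157 (88 higher, 69 lower), ratios within slides 75 (44 higher, 31 lower), and the assignments to cultures 27 to 94. Ratios within slides called 53 of the 96 called genes that had one, and all 96 kept the sign. Of the 102 genes, 23 were called in every assignment. No slide paired 15 min with the control.

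At 60 min, genes of the general stress response under RpoS had risen: 9 of 18 members passed (13 over the list alone, camera adjusted p = 5.47e-17; median log2 1.64), with osmY by 12.8-fold (log2 3.67 ± 0.36, adjusted p = 4.39e-06) and the pyruvate oxidase gene poxB by 5.11-fold. The Suf genes, a further system of iron-sulfur assembly, were higher as a list (2 of 6, or 6 over the list alone, adjusted p = 1.25e-05), with sufA by 8.08-fold (adjusted p = 0.0128; 0.0547 without the Cy3 control file of slide 16). Other large rises were those of soxS (15.1-fold), iscR (11.8-fold), cyoD (10.7-fold), puuA (9.28-fold) and ybaY (8.70-fold). The falls were led by gatZ (31.5-fold, log2 -4.98 ± 0.41, adjusted p = 1.73e-06), ydfZ (23.6-fold, log2 -4.56 ± 0.31, adjusted p = 2.57e-08), gatC (16.3-fold), gatY (15.4-fold), manY (14.4-fold), nmpC (13.8-fold), hyaA (13.4-fold) and ompW (12.7-fold). The methionine list was now lower than the control (5 of 12, adjusted p = 3.02e-06; median log2 -0.89), with metF 6.21-fold lower (adjusted p = 0.0193). For metE, 4.07-fold lower, the adjusted p of 0.0155 became 0.0602 without the Cy5 file of slide 96 at 60 min.

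At 60 min the cyo (4 of 4 higher, adjusted p = 1.41e-13), citric acid cycle (7 of 14, adjusted p = 2.74e-13), Isc (5 of 8, adjusted p = 3.59e-13), pyruvate dehydrogenase (3 of 4, adjusted p = 3.02e-06) and OxyR (1 of 11, or 5 over the list alone, adjusted p = 0.000803) lists were also higher. Nitrate and nitrite respiration (5 of 15, adjusted p = 3.40e-08), hydrogenases (5 of 17, adjusted p = 1.10e-07), glucose phosphotransferase uptake (4 of 6, adjusted p = 0.000124) and fumarate, DMSO and TMAO respiration (2 of 11, adjusted p = 0.00105) were lower. In all 141 genes passed, 82 higher and 59 lower, of which 57 passed at no earlier time. The slide block called 324 (179 higher, 145 lower) and ratios within slides 174 (108 higher, 66 lower). Ratios within slides called 113 of the 133 called genes that had one, and all 133 kept the sign. Without slides 96 and 98 the count was 64, and the assignments to cultures gave 35 to 150, with 28 of the 141 genes called in every assignment.

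**Figure D2:**
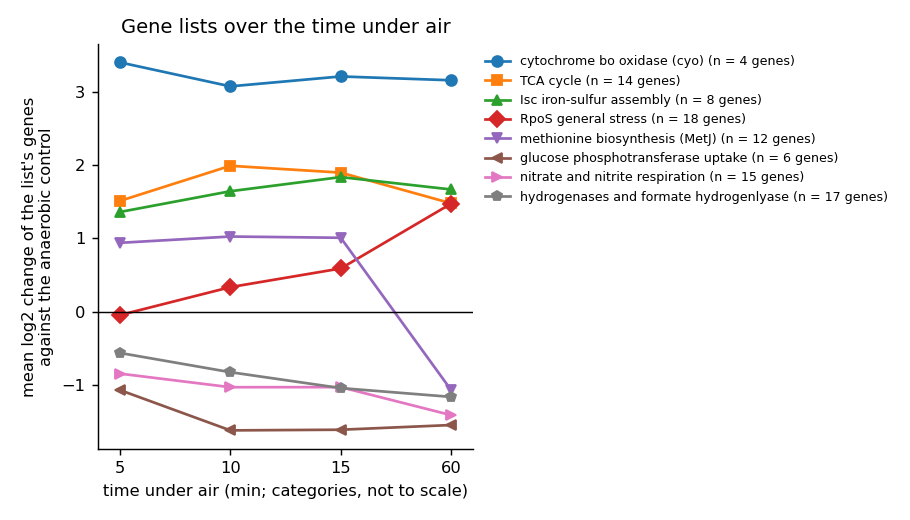
Mean log2 change of the tested genes of 8 lists against the anaerobic control, at each time under air (categories, not to scale). The methionine list lies above 0 from 5 to 15 min and below 0 at 60 min, and the RpoS list is highest at 60 min.

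All list calls given above held with an estimated correlation. The following calls were made with the preset correlation, and each adjusted p is followed by the adjusted p with an estimated correlation. Glycolysis was lower at 5 min (adjusted p = 0.000135, and 0.145 with an estimated correlation; gapA was 3.12-fold lower), 10 min (0.000923 and 0.217), 15 min (0.00228 and 0.262) and 60 min (0.0155 and 0.370). The Gad acid resistance list, with no member past the gene test, was lower at 5 min (0.0166 and 0.301), 10 min (0.00143 and 0.155) and 15 min (0.0391 and 0.370). Branched-chain amino acid biosynthesis was lower at 10 min (0.0106 and 0.262), 15 min (0.0163 and 0.297) and 60 min (0.00239 and 0.173), and the cytochrome bd oxidases at 10 min (0.0149 and 0.102) and 15 min (0.0132 and 0.0961). Ribosomal protein genes were lower at 10 min (0.0448 and 0.779), the nuo genes of NADH dehydrogenase at 15 min (0.0377 and 0.0638), and fermentation genes at 15 min (0.0391 and 0.218) and 60 min (0.0119 and 0.124). At 60 min the ATP synthase (0.0153 and 0.370) and cysteine (2.65e-05 and 0.0760) lists were lower and aerobic ribonucleotide reduction higher (0.00456 and 0.0638), and the RpoS list was higher at 15 min (7.56e-05 and 0.137). Several of these calls also ended without a single file. Ribosomal proteins reached 0.591 without the Cy3 file of slide 57 at 10 min and turned in direction without slides 96 and 98 (higher, 0.920), Gad at 5 min 0.333 without the Cy5 file of slide 12, and fermentation at 15 min 0.255 without the Cy5 file of slide 14.

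Maltose and ribose transport was lower at 5 min (adjusted p = 0.0314, and 0.0913 with an estimated correlation), 10 min (0.0221 and 0.0728), 15 min (0.00348 and 0.0169) and 60 min (0.00397 and 0.0185). Of 34 alternatives, the calls held in 17 at 5 min, 22 at 10 min, 31 at 15 min and 32 at 60 min. At 5 and 10 min they also ended with only genes well above background, with all spots and without single exposed files. Single control files ended the call at every time. Without the Cy5 control file of slide 56 the adjusted p was 0.872 (with the direction turned), 0.941, 0.626 and 0.586, and without the Cy3 control file of slide 16 it was 0.406, 0.344, 0.102 and 0.133.

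Lists with no call at any time included the SoxRS regulon (lowest adjusted p 0.0734, at 60 min, with 2 of 16 members higher), iron uptake under Fur, flagella and chemotaxis, heat shock, SOS, cytochrome c maturation, and the glyoxylate and acetate list (lowest adjusted p 0.0706, at 15 min). The RpoS list had no call at 5 min, with a median log2 change of 0.01 and a mean below 0.

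The change between times was tested directly. Between 15 and 60 min, 15 genes changed, 14 lower and 1 higher. The largest falls were those of metF (21.4-fold, log2 -4.42 ± 0.48, adjusted p = 0.000191), metE (20.6-fold, log2 -4.37 ± 0.48, adjusted p = 0.000122), metR, a regulator of methionine synthesis (7.48-fold), ydfZ (6.97-fold, adjusted p = 8.06e-05) and cbl, a regulator of sulfur assimilation (6.01-fold). The gene higher at 60 min was ldtE (2.43-fold, adjusted p = 0.0155; 0.0756 without the Cy3 file of slide 13 at 15 min and 0.0522 without the Cy5 file of slide 96 at 60 min). The methionine (6 of 12 lower, adjusted p = 3.08e-28) and cysteine (4 of 24 lower, adjusted p = 8.43e-13) lists fell, and the RpoS (adjusted p = 1.85e-14) and Suf (adjusted p = 4.78e-07) lists rose with no member past the gene test over all genes (8 of 18 and 3 of 6 over the list alone). These 4 calls held with an estimated correlation. The citric acid cycle list was lower (0.0115; 0.539 with an estimated correlation). The slide block called 59 genes (23 higher, 36 lower), ratios within slides 25, and the assignments to cultures 3 to 12. Of the 15 genes, 3 were called in every assignment. The count was 7 without the Cy3 file of slide 13, 9 without the Cy5 file of slide 14, 9 without the Cy5 file of slide 16 and 8 without the Cy3 file of slide 14.

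Between 5 and 60 min, 54 genes changed, 34 higher and 20 lower. Falls included metF (27.4-fold, adjusted p = 7.10e-05), ydfZ (15.5-fold, adjusted p = 2.92e-07), metE (12.7-fold) and metR (8.22-fold), and rises poxB (5.36-fold, adjusted p = 0.00875). The RpoS list rose (10 of 18, adjusted p = 1.36e-21) and so did the Suf list (2 of 6, adjusted p = 6.51e-07), and the methionine list fell (6 of 12, adjusted p = 8.50e-19). Hydrogenases were lower (2 of 17, adjusted p = 0.00756; 0.0890 without the Cy3 file of slide 54 at 60 min). Nitrate and nitrite respiration was lower too (1 of 15, adjusted p = 0.0135), with 0.0780 without the Cy5 file of slide 12 at 5 min, 0.0794 without the Cy3 file of slide 61 at 15 min, 0.0857 without the Cy5 file of slide 96 at 60 min and 0.204 without slides 96 and 98. It was 0.0898 without background correction and 0.0703 with only genes well above background. These 5 calls held with an estimated correlation. Lower with the preset correlation alone were the cysteine (0.000606, and 0.327 with an estimated correlation), OxyR (0.0134 and 0.202) and histidine (0.0421 and 0.145) lists. The OxyR call ended without any 1 of 5 of the 20 files, with an adjusted p of up to 0.157, and the histidine call without any 1 of 8, up to 0.0903. The slide block called 111 genes (75 higher, 36 lower), ratios within slides 23, and the assignments to cultures 3 to 47. Within slides, 9 of the 23 were higher and 14 lower, so the majority turned from higher to lower. Among the 50 called genes with such a ratio, 17 were called there and all 50 kept the sign. Of the 54 genes, 3 were called in every assignment. The count was 31 without the Cy5 file of slide 12, 34 without the Cy3 file of slide 56, 31 without the Cy5 file of slide 57, 21 without the Cy5 file of slide 16 and 19 without the Cy3 file of slide 14.

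Between 5 and 10 min, 1 gene changed in limma, gatC (log2 -2.26 ± 0.38, adjusted p = 0.0441), with 82 genes at an unadjusted p under 0.05 and 4 called with the slide block. Its adjusted p was above the threshold without any 1 of 12 of the 20 files, up to 0.267. The RpoS (adjusted p = 0.00280, and 0.511 with an estimated correlation), cysteine (0.0111 and 0.511), citric acid cycle (0.0260 and 0.640) and Isc (0.0421 and 0.539) lists were higher at 10 than at 5 min. Each of these calls ended without single files: RpoS without 2 of the 20 (adjusted p up to 0.314), cysteine without 9 (up to 0.162), the citric acid cycle without 8 (up to 0.638) and Isc without 8 (up to 0.347).

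Between 10 and 15 min the OxyR list fell (adjusted p = 0.000272, and 0.0261 with an estimated correlation), with 0.133 without the Cy3 file of slide 13 at 15 min and 0.0636 with all spots kept. The RpoS (0.00286, and 0.511 with an estimated correlation) and nucleoside (0.0435 and 0.511) lists were higher and fumarate, DMSO and TMAO respiration lower (0.0159 and 0.0769). These calls ended without any 1 of 3 files (up to 0.283), 14 files (up to 0.756) and 5 files (up to 0.0911). limma called 0 genes, with 37 at an unadjusted p under 0.05 and 0 called with the slide block or with ratios within slides.

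**Figure D3:**
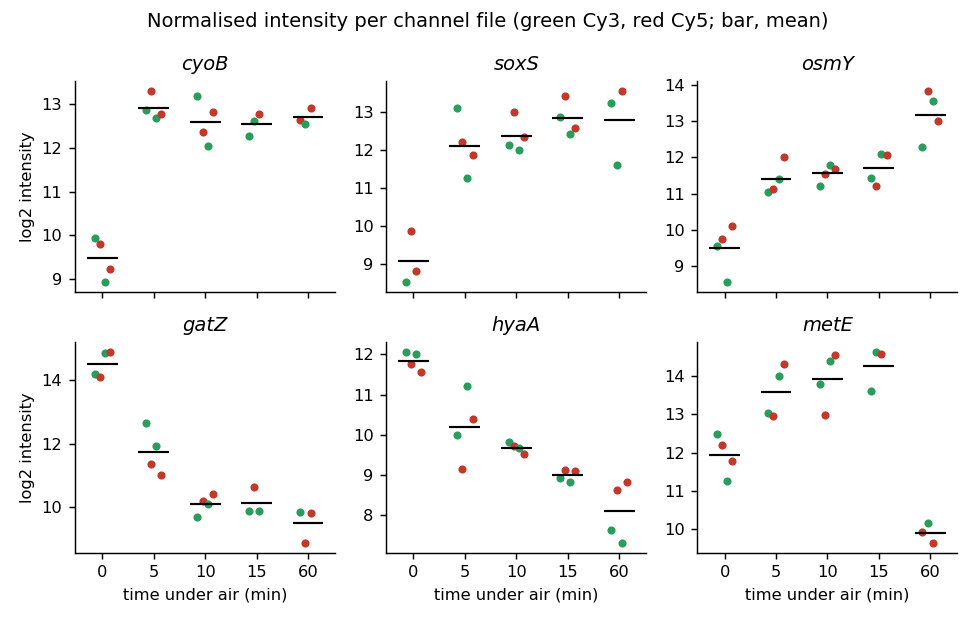
Normalised log2 intensity of 6 genes in each channel file by time under air, with 0 for the anaerobic control, green for Cy3, red for Cy5 and a bar for the mean of the group. Values of spots marked poor or negative are missing. For metE the files at 60 min lie below all control files and the files at 5, 10 and 15 min above them.

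Across the 4 times, 185 genes passed at 1 or more, and 49 passed at every time, 27 higher and 22 lower. The genes higher at every time included cyoA, cyoB, cyoC, cyoD, iscR, iscS, icd, aceE, soxS and osmY, and those lower included gatZ, gatY, nrfA, nirD, narG, hypB, frdB, gapA and malE. The genes metE, metF and metR were called higher at an earlier time and lower at 60 min. The calls at 5 and 10 min shared 32 higher and 25 lower genes, against 0.591 and 0.447 for independent lists and a mean of 0 in simulated unchanged groups, which had at most 1 call at any time and so do not measure what the shared control adds, and those at 15 and 60 min shared 35 and 40, against 1.33 and 0.999. Changes correlated across genes, which are not independent replicates, with r = 0.810 between 5 and 10 min (simulated 0.592, covariance 0.426 against 0.158) and r = 0.738 between 15 and 60 min (simulated 0.589, covariance 0.409 against 0.158). Part of the excess of shared calls may come from the shared control. The times of these pairs also lay together on slides (12 and 57, and 54 and 14), which was not separated from it. At 5 and 60 min, which shared no slide, the calls had 27 higher and 25 lower genes in common and 1 opposite. Their changes correlated with r = 0.575 (simulated 0.297).

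The deposited log2 ratios had the sign of the recomputed change for all called genes with a value, 61, 104, 102 and 141 at the 4 times. Over all genes with a value the share was 85.75%, 87.81%, 87.61% and 86.67%. The direction of the deposited ratios was to be settled against these same changes. Their direction as a whole is therefore no separate support. Across about 3068 genes, Pearson's r was 0.881 at 5 min, 0.907 at 10 min, 0.909 at 15 min and 0.922 at 60 min, with Spearman's rho of 0.851, 0.887, 0.881 and 0.875. These are correlations across genes made from the same scanner files.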

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

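The tests of the methionine pattern, of a spot or slide effect on slides 96 and 98, and of the spread of the genes left out were chosen after the results were seen.

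Methionine genes lay above the control from 5 to 15 min and below it at 60 min, and the difference between 60 and 15 min was itself past the threshold for metE (adjusted p = 0.0001215 in limma), metF (0.0001909) and metR (0.0002882). Against an origin in slides 96 and 98, the list's mean change from 15 to 60 min without them was -1.488 (camera adjusted p = 2.36e-10, over 8 genes), against -1.66 for the same genes and -2.08 for all 12 genes with every slide. Slide 98 held no file of these times, so this covers the drop alone. The list's calls against the control, higher at 5, 10 and 15 min and lower at 60 min, held in 34 of 34 alternatives. Leaving out both slides was 1 of them. The overlapping grouping by the name met, given below, lost its calls against the control with an estimated correlation. Against differences between slides, the slides that paired 60 with 15 min gave mean ratios of -1.71 and -2.10 on the log2 scale, below 0 for 11 of 12 and 10 of 10 genes. A change with the time under air and a difference between the cultures sampled at these times both stay open: the list means of the 4 files at 60 min lay below those of the 4 at 15 min, but the exact permutation p of 0.0286 (two-sided) counts files as independent, and with 2 cultures per time the smallest is 0.333.

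Of the 4 files of slides 96 and 98, 3 had the largest residual standard deviations of all 20. Dim signal is argued against, because among the brighter genes their median residual standard deviation was still 0.736, against 0.343 to 0.596 in the other files. The 4 files ranged from 0.512 to 0.806, so the lowest lay within the range of the other files. An effect of the spot or slide shared by both channels and a control culture that stands apart cannot be told apart: the residuals of both channels correlated at 0.632 on slide 98 and 0.736 on slide 96, against 0.358 to 0.664 on the other slides, and those of the control files of both slides at 0.227.

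With every spot kept whatever its mark, 24, 43, 42 and 52 of the 1139 genes left out were past the threshold at 5, 10, 15 and 60 min, 76 genes in all, among them, named after their values were seen, gatA, sdhB, nirB, cyoE and metB. Signal at the background is argued against, since 88.3% of their poor or negative values lay well above the local background. The share was 85.4% for all poor or negative values and 74.8% for the other values, so it is not particular to these genes. Noisier values stay open: their median residual standard deviation was 0.983 times that of the tested genes called in the same fit (95% bootstrap interval over genes 0.918 to 1.09). That comparison replaced an earlier one with all tested genes, which gave 0.811, because called genes are selected for a small spread, and a later one of all genes left out with all genes tested, which gave 1.03. No biological explanation was tested.

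Changes between times were called for 15 genes between 15 and 60 min, 54 between 5 and 60 min and 1 between 5 and 10 min. Of 366 sets of 4 values, 14 held 1 value far from the other values by Dixon's ratio, where chance gives about 18.3. These were, for file measures, the median background of the Cy3 file of slide 57 at 10 min (ratio 0.898), the percent of spots well above background of the Cy3 file of slide 56 at 5 min (0.832) and the residual standard deviation of the Cy3 file of slide 98 at 5 min (0.846). For list means they were the Isc (0.852) and citric acid cycle (0.836) lists in the Cy5 file of slide 96 at 60 min and the fumarate, DMSO and TMAO list in the Cy3 file of slide 61 at 15 min (0.831). For genes they were katG at 10 min (0.899), metR at 5 min (0.863), gatB at 60 min (0.982), nrfA in the control (0.852), frdB at 60 min (0.907), focA at 60 min (0.876), ptsH at 15 min (0.865) and nuoE at 10 min (0.854).

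Other splits of the 8 files of a comparison into 4 and 4, 35 in all, treat repeats of the same culture as independent. With 2 cultures against 2 there are 3 splits, too few for a share under 0.05. For genes, the real count, the highest of the other splits and the number of splits as large were 61, 90 and 3 at 5 min, 104, 2 and 1 at 10 min, 102, 3 and 1 at 15 min and 141, 196 and 2 at 60 min. Between 5 and 10 min they were 1, 3 and 3, between 10 and 15 min 0, 0 and 35, between 15 and 60 min 15, 3 and 1, and between 5 and 60 min 54, 0 and 1. For lists they were 12, 15 and 4 at 5 min, 15, 16 and 3 at 10 min, 18, 17 and 1 at 15 min and 19, 18 and 1 at 60 min.

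The split with 196 calls at 60 min sets the files of slides 96, 98 and 54 against those of slides 16, 56 and 14. This follows the chains of slides found from the data, whose origin is open, and the split by them gave 82 calls at 5 min, 0 at 10 min and 0 at 15 min. With the chain as a fixed block, 79, 138, 144 and 189 genes were called at 5, 10, 15 and 60 min, and with dye-swap files averaged within chains, 12, 17, 27 and 35.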

How the results depend on the processing

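The rules and the alternatives were fixed before the data were examined, except for the alternatives named here as added. No paired analysis was possible because the headers give no culture numbers, so that cultures could not be joined across groups; files of the same slide were joined in the slide block and in ratios within slides. For the same reason a fit with the culture as a random block or as a replicate block, and averaging known dye-swap pairs, were not run. Signal over background limits the dim genes: a file had 56.5% to 92.6% of its spots well above background.

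Counts at 5, 10, 15 and 60 min stayed within 1.5 times of 61, 104, 102 and 141 without background correction, with an offset of 10, with cyclic loess, with median centring and with a minimum change. With the slide as a random block they were 130, 158, 157 and 324. With only the groups compared they were 18 at 5 min, 51 at 10 min and 36 at 60 min, with fewer files to estimate the spread. Counting deposited ratios of at least 1 in size, with no test, gave 314, 488, 417 and 345. Among the added alternatives, all spots gave 101, 169, 171 and 245, of which 24, 43, 42 and 52 were genes otherwise left out; ratios within slides gave 52 at 10 min; leaving out slides 96 and 98 gave 38 at 5 min and 64 at 60 min, with fewer files. Dye-swap means, with fewer units than channel files, gave 12, 17, 27 and 35 at the fewest. At the most they gave 55, 120, 94 and 150. Joined within chains of slides they gave 12, 17, 27 and 35, the fewest of the 32 assignments at every time. All 32 assignments have the same number of units, so that number does not account for the difference between them. If the chains are cultures, which is open, the lower counts would be those at the level of cultures. Single files left out gave 42 to 59, 74 to 104, 77 to 98 and 99 to 143.

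Between 5 and 10 min the count of 1 became 0 with an offset of 10, with only the groups compared, all spots, empty spots left out, without slides 96 and 98, with the chain as a block and with dye-swap means under any assignment or within chains, 2 with cyclic loess (1 higher, 1 lower) or ratios within slides, 4 with the slide block, and 0 to 1 without single files. The cause was not tested. Between 10 and 15 min it was 0 throughout. Between 15 and 60 min the 15 became 59 with the slide block, 7 with only the groups compared, 26 with all spots, 25 with ratios within slides, 23 with the chain as a block, 4 with dye-swap means within chains, 3 at the fewest assignments, and 7 to 17 without single files. Without background correction the share of higher genes was 25% in place of 6.67%. Between 5 and 60 min the 54 became 111, 3, 107, 23, 84, 3 and 3 in the same order, and 19 to 58 without single files. The cause was not tested.

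With an estimated correlation, 9 lists were called at 5 min, 9 at 10 min, 11 at 15 min and 13 at 60 min, in place of 12, 15, 18 and 19. Single files left out gave 11 to 15, 13 to 19, 14 to 19 and 17 to 22. The overlap of 49 genes at all times became 84 with the slide block, 11 with only the groups compared, 84 with all spots, 26 without slides 96 and 98, 10 with dye-swap means at the fewest and within chains, and 35 to 48 without single files. Pearson's r with the deposited ratios became 0.846, 0.866, 0.868 and 0.892 without background correction, and 0.891 at 5 min with cyclic loess. The cause was not tested.

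Of 859 results on named genes, 236 were called. Over all alternatives these gave 7670 values, of which 6733 kept direction and call, 937 kept the direction and lost the call, and 0 reversed. In 63 the call held in every alternative. Many alternatives leave out only 1 file or rescale the same values. The largest rises and falls were also named for files that did not overlap between the groups compared. The 0 reversals are therefore little separate support. Of the 623 that were not called, 1 turned round: cysK at 15 min, lower and not called, was higher in ratios within slides (log2 1.99, adjusted p = 0.0364). The cause was not tested.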

Other observations

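Genes were also grouped by the first 3 letters of their names, a grouping chosen after the data were seen. Of 255 such families, 27 passed camera at 1 or more times against the control. The gat family was lower at each time (median log2 -2.27, -3.67, -4.13 and -3.99). The fru family, of fructose uptake, was lower too (median log2 -1.69, -2.19, -1.23 and -1.40, adjusted p = 0.00156, 0.000265, 0.00136 and 0.00462). The man family, of mannose uptake, was lower from 10 min (median log2 -2.05, -2.10 and -1.62, adjusted p = 0.00294, 0.0116 and 0.00426). These calls held with an estimated correlation.

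Families that rose included puu, of putrescine breakdown (median log2 1.99 at 15 min, adjusted p = 8.52e-06, and 0.00992 with an estimated correlation), osm, of genes induced by osmotic stress (median log2 1.79 at 60 min, adjusted p = 4.42e-08), and lld, of lactate use (median log2 1.60 at 5 min, adjusted p = 0.00419, and 0.0792 with an estimated correlation). The mhp family, of phenylpropionate breakdown, fell between 15 and 60 min (median log2 -1.21, adjusted p = 4.10e-07). The met family, of 11 genes, was higher at 5, 10 and 15 min and lower at 60 min. Its camera adjusted p was 1.91e-05, 2.18e-05, 1.91e-05 and 1.67e-05. Unlike the methionine list, it lost these calls with an estimated correlation (0.0734, 0.0750, 0.0734 and 0.0700). Its fall between 15 and 60 min held (8.01e-09 with an estimated correlation).

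A hypothesis found from the data is that the files fall into chains of slides: slides 96, 98, 12, 61 and 54, and slides 16, 56, 57, 13 and 14. Residuals of files of the same group correlated by 0.574 more within a chain than across chains (means 0.00181 and -0.572). In 4 of 5 groups both pairs within a chain lay above every other pair. The chains were picked from these residuals, so neither result tests them. Residuals around the mean of a group also correlate negatively on average by construction. At 5 min, slides 98 and 12 of the same chain (-0.400) lay below slide 12 with slides 56 (-0.320) and 57 (-0.254) of the other. This may reflect a culture or a hybridisation round shared within a chain, which cannot be told apart, since no header gives either. The chains are a hint from the data and not the design. Across genes, the changes at 5, 10, 15 and 60 min correlated between the chains with r = 0.308, 0.302, 0.299 and 0.429.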
